A study of Mus musculus with 44 samples.

How the data were processed

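RNA-seq gene counts were analysed for 16 libraries of the mouse fibroblast line L929 (4 groups) and 28 libraries of primary mouse cortical neurons (7 groups), with 4 libraries in each group. Groups and replicate numbers come from the submitters' sample titles. Per the labels' protocols, messenger RNA was purified with poly-T beads, fragmented and copied with random hexamers, dexamethasone and peptide, in the groups given them, were applied for 4 hours, and libraries were sequenced on an Illumina instrument. Poly-T selection takes up replication-dependent histone transcripts poorly, since most of these lack a poly(A) tail. The concentration of dexamethasone is not given in the sources used here.

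The deposited values are raw, whole-number read counts per gene for 54532 genes, in one table for L929 and another for neurons. Alignment used HISAT2 2.2.1 and the genome build mm10, per the submitters' processing notes. The read counter, the annotation and the strand setting are not given in the sources used here. Of the gene identifiers in the tables, 99.9% were found in the GENCODE M21 primary annotation, and 98.3% of these had the same start and end. Strand being unstated, counts of overlapping or antisense genes cannot be separated, and counts of near-identical copies (histone genes, interferon-induced families, Serpina3 and Hspa1 genes, ribosomal protein copies) are uncertain. Every gene row had an identifier, and no column of other samples was present. Total counts were 17211270 to 18313407 in L929 and 13685236 to 17083701 in neurons. Without molecular identifiers, reads are not independent molecules, so the limit of 3 counts that a count of 0 allows covers counting error only.

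Each table was analysed alone. Low counts were removed with edgeR's filterByExpr, which left 14118 genes in L929 and 17837 in neurons, and libraries were scaled by TMM. Comparisons used edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood fits of all groups of a table, a group term and no replicate block, so that the groups share an estimate of the spread. The common biological coefficient of variation was 0.067 in L929 and 0.066 in neurons. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed, with no fold minimum. There were 13 comparisons between 2 groups, and a slope on log10 dose over the 20 interfering peptide libraries as the fourteenth result. Adjusted p values for genes come from this test unless another fit is named beside them.

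The report names Frmd5 and 5 glucocorticoid genes (Fkbp5, Tsc22d3, Per1, Sgk1, Nr3c1), members of the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 2 CPM and groups that do not overlap (the overlap was not asked of the trend), and up to 4 members with the smallest p of each gene list past its threshold. Predicted genes were skipped. Some genes that meet the rule are not reported here. This rule, the groups, the comparisons, the tests, the first set of alternatives and 26 gene lists were fixed before the data were examined. The lists hold glucocorticoid targets, pathway genes and cell type markers from textbook knowledge. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation was used as an alternative. Counts adjusted over the list alone use the same gene tests with the adjustment confined to the list's members.

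A glucocorticoid target score was the mean centred log2 CPM of the tested members of the glucocorticoid list, compared by an exact two-sided permutation test of 4 against 4 libraries and adjusted over 13 comparisons. Genes called for dexamethasone, at most 200 in each direction, gave scores whose correlation with log10 dose was tested with 100000 resamples and adjusted over both sets. Where both sides of a relation used the same control group, that group was split, with 2 libraries on each side.

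The steps were tested on simulated counts drawn from the real means and library sizes. Each simulated library was drawn independently, with 50 genes changed at each fold. The shares of false calls therefore do not cover libraries that resemble each other in pairs. In a simulated L929 comparison of delta-IDR with full-length, 54% of genes changed by 1.25-fold, 78% by 1.5-fold, 96% by 2-fold and 100% by 4-fold were recovered, and 4.1% of 171 calls were false. In a simulated neuron comparison of interfering with control peptide at 100 µM these shares were 48%, 72%, 74% and 100%, with 5.8% of 156 calls false, and for the trend 74%, 80%, 96% and 100%, with 6.4% of 187 false.

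Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of only the compared groups, a replicate block, each library left out in turn, dose as a rank, other list tests (fry, estimated correlation) and other score definitions. Added after seeing the data were sums of libraries 1 and 3 and of libraries 2 and 4 of each group, 1 sum per group, the trend without the 1 and 3 µM groups, genes of X and Y left out, further splits of shared groups, and a list of diencephalic genes, whose score also served as a covariate.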

Results

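Polyadenylated RNA was sequenced from 44 mouse libraries in 11 groups of 4. L929 is a fibroblast line from mouse connective tissue. Its 16 libraries formed a control group and 3 groups that carried FRMD5 isoform 2 constructs, as the full-length protein, with the intrinsically disordered regions deleted (delta-IDR), or with the coiled-coil and low-complexity domains deleted (delta-CC-LCD). FRMD5 is a FERM-domain protein of the cell cortex. The other 28 libraries came from primary cortical neurons of mice in 7 groups. Of these, 2 groups received a control peptide at 100 µM, without and with dexamethasone (DEX), a synthetic agonist of the glucocorticoid receptor, and 5 groups received DEX with an interfering peptide at 1, 3, 10, 30 or 100 µM. Total counts ran from 17211270 to 18313407 per L929 library and from 13685236 to 17083701 per neuron library. Values below are mean CPM (TMM-scaled counts per 1e+06 counts) ± SD and log2 changes ± standard error, with n = 4 libraries per group. The series title places the work in a study of how FRMD5 alters glucocorticoid receptor functions. The labels do not say that libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

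Frmd5 lies on chromosome 2 from 121545529 to 121807087, on the minus strand, in mm10. The L929 libraries held almost no reads on it, with 15 counts over the 4 control libraries, 9 in the full-length group, 20 in delta-IDR and 5 in delta-CC-LCD. Frmd5 was therefore not tested in L929, and its counts do not show which libraries carried a construct. In neurons Frmd5 was well expressed, at 83.1 ± 1.56 CPM with control peptide alone and 88.4 ± 3.33 CPM with DEX added (0.09 ± 0.05, adjusted p = 0.227). In the 5 interfering peptide groups its mean lay between 87.8 and 93.5 CPM. Frmd5 was higher with DEX and 100 µM interfering peptide than with control peptide and no DEX, by 0.17 ± 0.05 (adjusted p = 0.00446, and 0.0295 with the libraries summed in pairs). Against control peptide with DEX it did not pass at any dose, with an adjusted p of 0.232 at 100 µM, nor in the trend with dose (0.285).

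The first comparison set the L929 full-length group against the control group, whose labels do not say whether it received DEX. A difference in DEX and an effect of the construct therefore cannot be told apart here. Textbook glucocorticoid-induced genes were far higher in the full-length group. Sgk1, a serum- and glucocorticoid-regulated kinase, stood at 1074 ± 13.6 CPM against 29.6 ± 1.92 (log2 change 5.18 ± 0.05). Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose by 4.62 ± 0.06, and Errfi1, a feedback inhibitor of the EGF receptor, by 3.84 ± 0.04. Fkbp5, a co-chaperone that restrains the receptor, rose by 2.39 ± 0.04 and the clock gene Per1 by 1.90 ± 0.05, whereas Nr3c1, the receptor gene itself, changed by -1.13 ± 0.04. Of 29 glucocorticoid-induced genes tested, 26 rose and 2 fell, and 28 passed when adjusted over the list alone (adjusted p = 4.58e-16, and adjusted p = 0.022 with an estimated correlation).

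Among the largest rises of full-length over control were Rgs2, a regulator of G-protein signalling, by 5.86 ± 0.17 and Fam107a, a stress-induced actin-binding protein, by 5.92 ± 0.23. Hcar1, the lactate receptor, changed by -3.52 ± 0.15 and the apoptosis gene Bbc3 by -2.91 ± 0.14. Immediate-early genes, which neurons and fibroblasts switch on within minutes of a stimulus, rose in 15 of 22 and fell in 3, with 19 past the threshold when adjusted over the list alone. Arc rose by 4.01 ± 0.13, Fos by 2.62 ± 0.15 and Junb by 2.38 ± 0.08. That list had an adjusted p of 0.00156, and adjusted p = 0.38 with an estimated correlation. Interferon-response genes fell in 13 of 24 and rose in 0 (13 adjusted over the list alone), among them Irf1 at -1.84 ± 0.13 and Ifit2 at -1.72 ± 0.10 (adjusted p = 0.00156, and adjusted p = 0.38 with an estimated correlation). Heat-shock genes rose in 10 of 14 and fell in 1 (11 adjusted over the list alone), with Hspa8 at 1.15 ± 0.03 (adjusted p = 0.013, and adjusted p = 0.257 with an estimated correlation). Over all 14118 genes tested, 4283 rose and 4056 fell. The construct groups are described as examined after 4 hours of DEX, and the labels of the control group do not say whether it received DEX.

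Glucocorticoid-induced genes were also far higher than control in both deletion groups. In delta-IDR, 26 of the 29 glucocorticoid-induced genes rose and 3 fell, with 29 when adjusted over the list alone (adjusted p = 9.14e-14, and adjusted p = 0.0265 with an estimated correlation). Sgk1 rose by 4.94 ± 0.05, Tsc22d3 by 4.56 ± 0.06 and Fkbp5 by 2.10 ± 0.04. In delta-CC-LCD the counts were also 26 and 3 of 29, with 29 adjusted over the list alone (adjusted p = 3.91e-14, and adjusted p = 0.0358 with an estimated correlation). There Sgk1 rose by 4.94 ± 0.05, Tsc22d3 by 4.82 ± 0.06 and Fkbp5 by 2.64 ± 0.04. Nr3c1 changed by -1.07 ± 0.04 in delta-IDR and by -1.09 ± 0.04 in delta-CC-LCD. Targets of the SRF and YAP pathways, which follow actin tension, rose in 10 of 13 and fell in 1 in delta-IDR (11 adjusted over the list alone, adjusted p = 0.00145, and adjusted p = 0.0265 with an estimated correlation), led by Cyr61 at 4.64 ± 0.07. Interferon-response genes, 13 of which fell in full-length, rose in 20 of 24 and fell in 3 in delta-IDR against control (23 adjusted over the list alone, adjusted p = 3.22e-05, and adjusted p = 0.305 with an estimated correlation), with Ifi44 at 4.05 ± 0.11 and Ddx58 at 1.62 ± 0.08. In delta-CC-LCD 4 of the 24 rose and 7 fell (11 adjusted over the list alone, adjusted p = 0.417). Hypoxia and glycolysis genes fell in 20 of 22 and rose in 1 in delta-IDR against control (21 adjusted over the list alone, adjusted p = 2.08e-06, and adjusted p = 0.376 with an estimated correlation), and fell in 19 and rose in 2 in delta-CC-LCD (21 adjusted over the list alone, adjusted p = 0.00765, and adjusted p = 0.688 with an estimated correlation). Nos2, inducible nitric oxide synthase, changed by -3.40 ± 0.27 in delta-IDR and by -5.37 ± 0.34 in delta-CC-LCD. In all, 9099 genes differed from control in delta-IDR, 4633 higher and 4466 lower, and 9120 in delta-CC-LCD, 4501 higher and 4619 lower.

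The mean of the centred log2 CPM of the 29 genes gave each library a glucocorticoid target score. It was -1.69 ± 0.04 (SD, n = 4) in L929 control, 0.63 ± 0.04 in full-length, 0.40 ± 0.02 in delta-IDR and 0.66 ± 0.06 in delta-CC-LCD. By an exact two-sided permutation test each construct group differed from control, and delta-IDR from full-length and from delta-CC-LCD, with p = 0.0286, the smallest that 4 against 4 libraries can give. Adjusted over the 13 comparisons between groups this became 0.0743 (exact permutation test), which misses 0.05. The score of delta-CC-LCD minus that of full-length was 0.03, with an exact permutation p of 0.457.

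**Figure D1:**
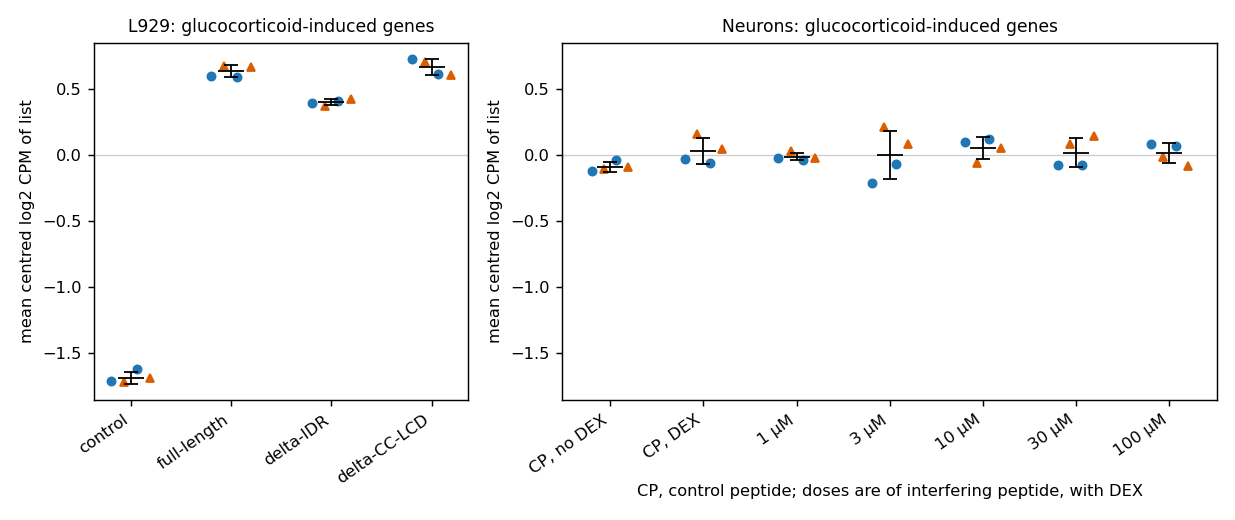
Glucocorticoid target score (mean centred log2 CPM of 29 textbook genes) in each L929 library (left) and each neuron library (right), by group, with circles for replicates 1 and 3, triangles for replicates 2 and 4, and bars for mean ± SD. The 4 L929 control libraries average -1.69 and every other L929 group lies above 0, while the neuron groups differ little on the same scale.

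Deleting the disordered regions was compared with the full-length construct to ask what these regions contribute. Interferon-response genes were higher in delta-IDR in all 24 of 24 members tested (24 adjusted over the list alone), with a median log2 change of 3.07 (adjusted p = 1.03e-33, and adjusted p = 0.00401 with an estimated correlation). Ifi44 stood at 103 ± 10.8 CPM against 4.93 ± 0.35 (4.38 ± 0.12), and the antiviral genes Ifit1 at 4.78 ± 0.39 and Rsad2 at 4.57 ± 0.27 were among the largest rises. The RNA sensor Ddx58 rose by 2.18 ± 0.08 and the chemokine Ccl5 by 4.70 ± 0.30. Ifit1 and Ifit3, and Oasl1 and Oasl2, belong to families of similar genes, so single members are uncertain.

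Hypoxia and glycolysis genes fell in 18 of 22 and rose in 0 in delta-IDR against full-length (19 adjusted over the list alone). Car9, a hypoxia-induced carbonic anhydrase, went from 800 ± 143 to 139 ± 51.3 CPM (-2.53 ± 0.36), and Pdk1, which limits pyruvate entry into mitochondria, changed by -1.67 ± 0.15. The list's adjusted p was 6.03e-17, and adjusted p = 0.0999 with an estimated correlation. S-phase genes rose in 19 of 20 and fell in 0 (19 adjusted over the list alone), with the replication licensing factor Cdt1 at 0.85 ± 0.06 and Mcm5 at 0.58 ± 0.05 (adjusted p = 2.22e-15, and adjusted p = 0.0776 with an estimated correlation). Ribosomal protein genes fell in 18 of 28 and rose in 0 (21 adjusted over the list alone), by a median of -0.21 (adjusted p = 3.22e-08, and adjusted p = 0.256 with an estimated correlation). Genes of the ER stress response, chaperones of the secretory pathway, rose in 11 of 18 and fell in 1 (12 adjusted over the list alone, adjusted p = 2.33e-05, and adjusted p = 0.0776 with an estimated correlation), with Pdia4 at 0.42 ± 0.04. NF-kB and inflammatory genes rose in 10 of 17 and fell in 1 (12 adjusted over the list alone, adjusted p = 1.13e-05, and adjusted p = 0.0776 with an estimated correlation), with Ccl2 at 0.65 ± 0.08.

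Glucocorticoid-induced genes were lower in delta-IDR than in full-length by modest amounts. Of 29 genes, 15 fell and 1 rose (19 adjusted over the list alone), with a median of -0.30 (adjusted p = 7.42e-07, and adjusted p = 0.0776 with an estimated correlation). The MAP kinase phosphatase Dusp1 changed by -0.63 ± 0.06, Nfkbia by -0.46 ± 0.05, Fkbp5 by -0.29 ± 0.04 and Sgk1 by -0.24 ± 0.04. Tsc22d3 (-0.06 ± 0.05, adjusted p = 0.412) and Per1 (-0.02 ± 0.05, adjusted p = 0.823) did not pass. In all, 1651 genes rose and 1917 fell. Of the 7769 genes that full-length libraries 1 and 3 called against control, 54.1% moved in the opposite direction in delta-IDR against full-length libraries 2 and 4, with a median signed change of -0.02.

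The domain deletion in delta-CC-LCD was compared with full-length in the same way. Immediate-early genes fell in 10 of 22 and rose in 0 (11 adjusted over the list alone), with Egr1 from 191 ± 29.5 to 64.3 ± 11.5 CPM (-1.57 ± 0.14), Fos at -1.10 ± 0.13 and Klf4 at -0.64 ± 0.11 (adjusted p = 6.76e-04, and adjusted p = 0.52 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 18 and fell in 0 (15 adjusted over the list alone), among them the squalene epoxidase Sqle at 0.44 ± 0.05 and Lss at 0.31 ± 0.05 (adjusted p = 1.02e-09, and adjusted p = 0.52 with an estimated correlation). Hypoxia and glycolysis genes fell in 14 of 22 and rose in 1 (15 adjusted over the list alone), with Tpi1 at -0.75 ± 0.13 and Pkm at -0.54 ± 0.09 (adjusted p = 1.59e-06, and adjusted p = 0.52 with an estimated correlation). Interferon-response genes rose in 12 of 24 and fell in 0 (16 adjusted over the list alone), by a median of 0.49 (adjusted p = 2.79e-07, and adjusted p = 0.52 with an estimated correlation), with Isg15 at 1.03 ± 0.22.

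Single glucocorticoid targets moved apart in delta-CC-LCD against full-length. Fkbp5 rose by 0.25 ± 0.04 and Tsc22d3 by 0.20 ± 0.05, while Sgk1 changed by -0.24 ± 0.04 and Per1 was at -0.07 ± 0.05 (adjusted p = 0.337). Over the list 9 of 29 rose and 9 fell (20 adjusted over the list alone, adjusted p = 0.949), the median being -0.01 and the mean 0.03. Notch4, a receptor of endothelial cells, rose by 1.24 ± 0.11, and Klhl3, an adaptor of a ubiquitin ligase, changed by -1.89 ± 0.20. In all, 1189 genes rose and 1538 fell. Of the 7769 genes that full-length libraries 1 and 3 called against control, 39.4% moved in the opposite direction in delta-CC-LCD against libraries 2 and 4. The median signed change was 0.05. With libraries 1 and 3 and libraries 2 and 4 of each group summed, 1501 genes passed.

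The deletions were also compared with each other. Interferon-response genes were higher in delta-IDR than in delta-CC-LCD in 24 of 24 members (24 adjusted over the list alone, adjusted p = 1.75e-28, and adjusted p = 0.00832 with an estimated correlation), with a median of 2.30. SRF and YAP targets rose in 7 of 13 and fell in 1 (8 adjusted over the list alone, adjusted p = 3.58e-04, and adjusted p = 0.019 with an estimated correlation), including Srf itself at 0.48 ± 0.05 and Tpm1 at 0.43 ± 0.05. Glucocorticoid-induced genes fell in 16 of 29 and rose in 2 (18 adjusted over the list alone, adjusted p = 3.38e-05, and adjusted p = 0.138 with an estimated correlation), with Fkbp5 at -0.54 ± 0.04, Hif3a at -0.82 ± 0.10 and Sgk1 not past the threshold (0.00 ± 0.04, adjusted p = 0.976). Astrocyte markers, several of which fibroblasts also express, fell in 5 of 10 and rose in 0 (5 adjusted over the list alone, adjusted p = 0.00993, and adjusted p = 0.166 with an estimated correlation), with the folate enzyme Aldh1l1 at -0.54 ± 0.06. In all, 1631 genes were higher in delta-IDR and 1516 lower, and 2084 passed with the libraries summed in pairs.

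**Figure D2:**
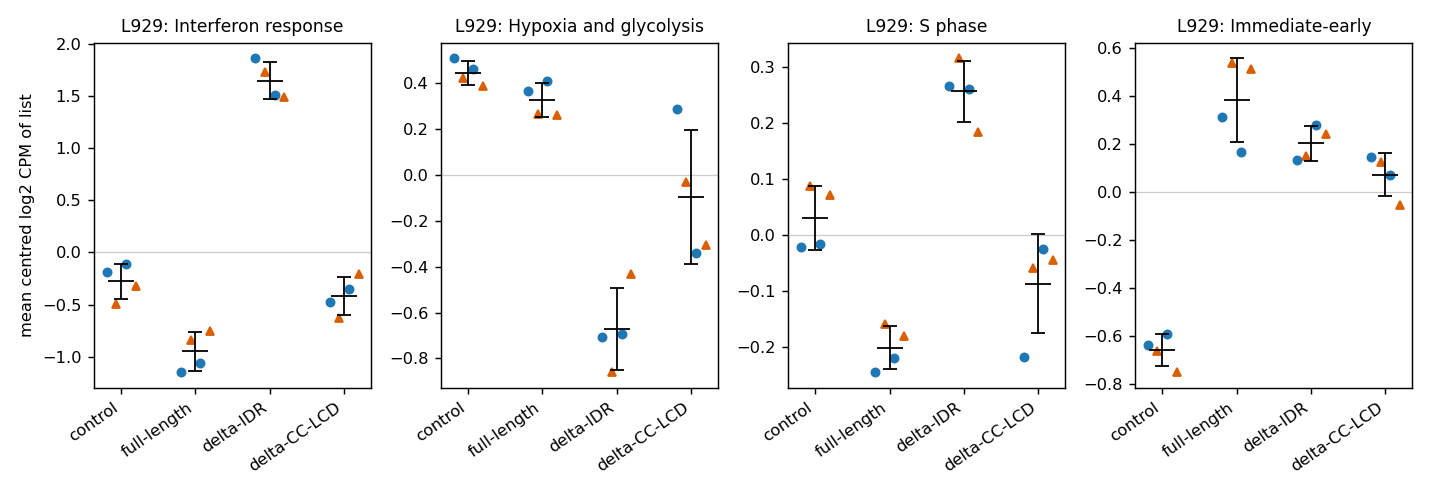
Mean centred log2 CPM of the interferon-response, hypoxia and glycolysis, S-phase and immediate-early lists in each L929 library, by group, with circles for replicates 1 and 3, triangles for replicates 2 and 4, and bars for mean ± SD. The delta-IDR libraries average 1.64 on the interferon list, above every library of the other 3 groups, and -0.67 on the hypoxia list.

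Some lists did not pass in any L929 comparison. Their smallest adjusted p values by camera were 0.0739 for p53 targets, 0.0807 for microglial markers, 0.0972 for neural progenitor markers, 0.158 for excitatory synapse genes, 0.206 for genes of the mitochondrial genome, 0.355 for extracellular matrix genes and 0.843 for oligodendrocyte markers. Nuclear genes of oxidative phosphorylation rose in 13 of 22 and fell in 0 in delta-IDR against control (13 adjusted over the list alone, adjusted p = 0.0382, and adjusted p = 0.508 with an estimated correlation), led by cytochrome c, Cycs, at 0.77 ± 0.04. Vascular and meningeal markers fell in 5 of 7 and rose in 0 in full-length against control (5 adjusted over the list alone, adjusted p = 0.0498, and adjusted p = 0.257 with an estimated correlation), with the growth factor receptor Pdgfrb at -1.33 ± 0.06.

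In neurons, DEX was compared with no DEX under the same 100 µM control peptide. The classical targets moved little. Fkbp5 stood at 102 ± 3.15 CPM with DEX and 101 ± 4.48 without (0.02 ± 0.05, adjusted p = 0.823), Sgk1 at 11.8 ± 1.38 and 12.6 ± 1.39 (-0.10 ± 0.11, adjusted p = 0.6), and Tsc22d3 at 50.3 ± 4.78 and 42.1 ± 4.64 (0.25 ± 0.10, adjusted p = 0.104). Per1 rose by 0.31 ± 0.08 and Hif3a by 0.79 ± 0.09, while Nr3c1 changed by -0.32 ± 0.10. Of 29 glucocorticoid-induced genes, 3 rose and 2 fell (5 adjusted over the list alone, adjusted p = 0.0829). The target score was 0.12 higher with DEX, with an exact permutation p of 0.0571, or 0.106 when adjusted.

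The largest decrease among the genes named by rule was that of the meiotic gene Sycp1, at -3.10 ± 0.36. Sycp1 stood at 6.04 CPM without DEX and 0.699 with DEX and control peptide, and at 3.59, 4.05, 3.11, 3.55 and 2.12 CPM with DEX and 1, 3, 10, 30 and 100 µM interfering peptide. Most of the other large decreases were replication-dependent histone genes of the Hist1 cluster, whose copies resemble one another, so that single members are uncertain. Hist1h1e went from 19.7 ± 1.84 to 4.38 ± 0.61 CPM (-2.17 ± 0.14) and Hist1h1d from 81.7 ± 9.92 to 27.7 ± 2.41 (-1.56 ± 0.09). The neuronal ubiquitin ligase Trim17 changed by -1.51 ± 0.12. Targets of ATF4, the transcription factor of the amino-acid stress response, rose in 11 of 20 and fell in 0 (18 adjusted over the list alone, adjusted p = 2.71e-10, and adjusted p = 0.393 with an estimated correlation), with asparagine synthetase, Asns, at 0.82 ± 0.20 and Shmt2 at 0.64 ± 0.14. Ctgf, a SRF and YAP target, rose by 1.02 ± 0.22, and the list rose in 4 of 13 and fell in 1 (5 adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.393 with an estimated correlation). Markers of inhibitory neurons rose in 6 of 16 and fell in 0 (6 adjusted over the list alone, adjusted p = 0.00382, and adjusted p = 0.393 with an estimated correlation). Genes of the mitochondrial genome rose in 7 of 13 and fell in 0 (7 adjusted over the list alone, adjusted p = 0.0037, and adjusted p = 0.393 with an estimated correlation). Their mean score was 0.04 ± 0.11 without DEX and 0.14 ± 0.12 with it, and -0.08 ± 0.05, -0.27 ± 0.29 and -0.08 ± 0.09 with DEX and 1, 3 and 10 µM interfering peptide. Receptor cofactors and chaperones rose in 2 of 19 and fell in 1 (5 adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.393 with an estimated correlation), the member that fell being Nr3c1.

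In all, 970 genes rose and 955 fell with DEX, and of those that changed at least 2-fold 13 rose and 231 fell. The libraries without DEX held 16992 to 17174 genes with 10 counts or more, against 16427 to 16536 with DEX, and 1.84% to 1.87% of their counts lay on long noncoding RNA genes, against 1.64% to 1.72%. In every one of the 7 neuron groups libraries 1 and 3, and libraries 2 and 4, were the most alike, and 330 genes passed when each such pair was summed. With 1 sum per group and the spread taken from the dose groups, 72 genes passed. Among these were Sycp1 (log2 change -3.10), Trim17 (-1.50), Hif3a (0.81) and the ATF4 target Shmt2 (0.65), and the thalamic gene Tcf7l2 (-1.99) headed them. Hist1h1e, Hist1h1d, Per1, Nr3c1, Ctgf and Asns were not among them, with log2 changes of -2.16, -1.55, 0.32, -0.30, 1.03 and 0.83. The spread of that fit takes in how far the dose groups depart from a line. Hist1h1e had 18.2 to 23 counts per 1e+06 counts in the libraries without DEX and 5.79 at most in any neuron library with DEX. Without the DEX library of replicate 1 the count was 1162. A score of 15 diencephalic genes, a list chosen after the values were seen, stood at 0.58 ± 0.88 without DEX and -0.45 ± 0.25 with it. Its member Tcf7l2, a thalamic transcription factor, averaged 88.1 CPM in no-DEX libraries 1 and 3 and 16.1 in libraries 2 and 4.

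The interfering peptide was compared with control peptide, both with DEX, at each dose. At 1 µM, hypoxia and glycolysis genes rose in 14 of 21 and fell in 0 (18 adjusted over the list alone, adjusted p = 1.36e-24, and adjusted p = 0.0111 with an estimated correlation), with Bnip3 at 0.60 ± 0.07, the collagen hydroxylase gene P4ha1 at 0.62 ± 0.07 and Pdk1 at 0.46 ± 0.06. Genes of the Y chromosome such as Ddx3y and Eif2s3y had 0 counts in all 4 libraries at 1 µM, which allows up to 3 counts in each, against 35.3 ± 3.39 and 45.8 ± 4.26 CPM with control peptide. At 3 µM the same genes were higher than with control peptide, Ddx3y by 1.41 ± 0.14, and Xist, the transcript of the inactive X chromosome, was at 1.02 ± 0.32 CPM against 1505 ± 70.9 with control peptide (named after its values were seen). At 1 µM Xist was at 2631 ± 85.2 CPM. These values point to female cells at 1 µM, male cells at 3 µM and both with control peptide. Kind of peptide, amount of peptide and mix of animals therefore cannot be told apart in these comparisons. Immediate-early genes rose at 3 µM in 11 of 24 and fell in 0 (14 adjusted over the list alone, adjusted p = 6.37e-16, and adjusted p = 0.0162 with an estimated correlation), with Fosb at 1.87 ± 0.12 and Fos at 1.83 ± 0.13. Cholesterol synthesis genes rose in 17 of 20 and fell in 0 at 3 µM (17 adjusted over the list alone, adjusted p = 4.1e-19, and adjusted p = 0.0162 with an estimated correlation). At 10 µM immediate-early genes rose in 18 of 24 and fell in 0 (21 adjusted over the list alone, adjusted p = 2.03e-33, and adjusted p = 5.12e-04 with an estimated correlation), with Npas4, an activity-dependent factor of neurons, at 1.80 ± 0.11. Cholesterol synthesis genes rose there in 15 of 20 and fell in 0 (18 adjusted over the list alone, adjusted p = 1.03e-22, and adjusted p = 0.00582 with an estimated correlation).

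Markers of inhibitory neurons fell at the low doses, in 6 of 16 at 1 µM (9 adjusted over the list alone, adjusted p = 9.44e-06, and adjusted p = 0.119 with an estimated correlation), 7 of 16 at 3 µM (8 adjusted over the list alone, adjusted p = 1.68e-04, and adjusted p = 0.206 with an estimated correlation) and 5 of 16 at 10 µM (6 adjusted over the list alone, adjusted p = 0.00271, and adjusted p = 0.267 with an estimated correlation), and rose in 0. The mean score of this list was 0.11 ± 0.10 in the control peptide group with DEX, which these comparisons share, and -0.03 ± 0.09 without DEX, against -0.04 ± 0.06, -0.04 ± 0.01 and -0.03 ± 0.10 at 1, 3 and 10 µM. Against the same group, genes of the mitochondrial genome fell in 3 of 13 at 1 µM (7 adjusted over the list alone, adjusted p = 1.09e-05, and adjusted p = 0.142 with an estimated correlation), 6 of 13 at 3 µM (7 adjusted over the list alone, adjusted p = 2.4e-08, and adjusted p = 0.0938 with an estimated correlation) and 5 of 13 at 10 µM (6 adjusted over the list alone, adjusted p = 7.59e-05, and adjusted p = 0.254 with an estimated correlation), and rose in 0. The numbers of genes past the threshold were 409 at 1 µM, 937 at 3 µM and 960 at 10 µM, and with the libraries summed in pairs 89, 101 and 108. At 1 µM the count was 228 without interfering replicate 2, 249 without interfering replicate 4 and 271 without control peptide replicate 2. At 3 µM it was 436 and 478 without control peptide replicates 2 and 4 and 568 without interfering replicate 2, and 370 when only these 2 groups were fitted. At 10 µM it was 479 and 515 without control peptide replicates 2 and 4, and 579, 632 and 613 without interfering replicates 1, 3 and 4. Several of the largest single changes, Tpm3-rs7, Rpl26 and AC149090.1, are copies of other genes and uncertain.

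At 30 µM the immediate-early genes rose in 19 of 24 and fell in 0 (20 adjusted over the list alone, adjusted p = 1.97e-26, and adjusted p = 0.00216 with an estimated correlation), with Egr1 at 2.72 ± 0.15 and Fosb at 2.77 ± 0.12. ATF4 targets fell in 15 of 20 and rose in 0 (18 adjusted over the list alone, adjusted p = 3.68e-11, and adjusted p = 0.288 with an estimated correlation), with Asns at -1.05 ± 0.20. Asns stood at 85.9 ± 7.01 CPM without DEX, 151 ± 18.6 with DEX and control peptide and 73.2 ± 24.1 at 30 µM. Fkbp5 changed by -0.34 ± 0.05 and Tsc22d3 by -0.47 ± 0.10, and Per1 rose by 0.37 ± 0.07. In all, 2833 genes passed, and 700 with the libraries summed in pairs.

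At 100 µM, the one dose at which both peptides were given, the largest rises were immediate-early and inflammatory genes. Egr1, an activity-induced transcription factor, went from 28.6 ± 1.85 to 234 ± 60.8 CPM (3.03 ± 0.15). Fos rose by 2.85 ± 0.12, Fosb by 2.68 ± 0.12, Npas4 by 2.43 ± 0.11 and the chemokine gene Cxcl1 by 3.28 ± 0.25. Immediate-early genes rose in 19 of 24 and fell in 0 (20 adjusted over the list alone, adjusted p = 4.95e-24, and adjusted p = 0.00372 with an estimated correlation). NF-kB and inflammatory genes rose in 12 of 16 and fell in 0 (12 adjusted over the list alone, adjusted p = 2.67e-07, and adjusted p = 0.0352 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 20 and fell in 0 (18 adjusted over the list alone, adjusted p = 7.23e-20, and adjusted p = 0.0113 with an estimated correlation), led by Hmgcs1 at 0.68 ± 0.04 and Sqle at 0.62 ± 0.04. Heat-shock genes rose in 8 of 16 and fell in 0 (8 adjusted over the list alone, adjusted p = 4.9e-04, and adjusted p = 0.0388 with an estimated correlation).

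ATF4 targets fell at 100 µM in 17 of 20 and rose in 0 (18 adjusted over the list alone, adjusted p = 3.15e-10, and adjusted p = 0.361 with an estimated correlation), with Vldlr at -0.54 ± 0.06. These falls are against the control peptide group with DEX, in which ATF4 targets had risen over no DEX. Shmt2 stood at 81.8 CPM without DEX, 128 with control peptide and DEX and 75.4 ± 13.6 at 100 µM, and Vldlr at 122, 148 and 102. Hypoxia and glycolysis genes fell in 9 of 21 and rose in 1 (12 adjusted over the list alone, adjusted p = 2.76e-04, and adjusted p = 0.361 with an estimated correlation), with Pdk1 at -0.60 ± 0.06. The histone genes Hist1h1d (-2.35 ± 0.12) and Hist1h2ac (-1.98 ± 0.14) were among the largest decreases. FERM-domain and cortical cytoskeleton genes rose in 6 of 20 and fell in 0 (7 adjusted over the list alone, adjusted p = 0.0435, and adjusted p = 0.203 with an estimated correlation), with Rock2 at 0.29 ± 0.05. Fkbp5 changed by -0.33 ± 0.05 and Tsc22d3 by -0.55 ± 0.10, Per1 rose by 0.30 ± 0.07, and Sgk1 (0.17 ± 0.11, adjusted p = 0.275) and Nr3c1 (-0.08 ± 0.10, adjusted p = 0.612) did not pass. Of the 29 glucocorticoid-induced genes, 3 rose and 4 fell (7 adjusted over the list alone, adjusted p = 0.906). In all, 4167 genes passed, and 1788 with the libraries summed in pairs.

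To ask whether the peptide turned back the DEX response, genes were called for DEX with control peptide libraries 1 and 2 and compared at 100 µM against libraries 3 and 4. Of 1394 genes called, 44.6% moved against their DEX change, and the median change signed by the DEX direction was 0.03. With libraries 3 and 4 used to call, 509 genes were called, 40.5% moved against it and the median was 0.06. These splits part libraries that were the most alike. With libraries 1 and 3 used to call and 2 and 4 to compare, 31.7% of 1652 genes moved against their DEX change, with a median of 0.11, and with the reverse 47.3% of 859 genes, with a median of 0.02. Without the split, in which both changes share libraries, the median was -0.01 over 1925 genes and 51.9% moved against it.

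Neurons with 100 µM interfering peptide and DEX were also set against those with control peptide and no DEX. Hist1h1e changed by -4.11 ± 0.18 and Hist1h1d by -3.91 ± 0.11, and Cxcl1 rose by 3.48 ± 0.26 and Egr1 by 3.33 ± 0.15. Fkbp5 (-0.31 ± 0.05) and Tsc22d3 (-0.29 ± 0.10) lay below their levels without DEX, so their falls at 100 µM were not a mere return to those levels. Nr3c1 changed by -0.39 ± 0.10, Per1 rose by 0.61 ± 0.08, and Sgk1 (0.07 ± 0.11, adjusted p = 0.667) did not pass. Cholesterol synthesis genes rose in 18 of 20 and fell in 0 (18 adjusted over the list alone, adjusted p = 2.03e-16, and adjusted p = 0.0266 with an estimated correlation). Excitatory synapse and cortical projection genes rose in 11 of 24 and fell in 1 (12 adjusted over the list alone, adjusted p = 0.00584, and adjusted p = 0.335 with an estimated correlation). Oligodendrocyte markers fell in 6 of 12 and rose in 0 (6 adjusted over the list alone, adjusted p = 0.0238, and adjusted p = 0.335 with an estimated correlation). The diencephalic score stood at -0.70 in the first group and 0.58 in the second. In all, 6259 genes passed.

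Over the 20 interfering peptide libraries, a slope per 10-fold dose was fitted for each gene. Cxcl1 rose by 2.01 ± 0.13 per 10-fold dose, Egr1 by 1.51 ± 0.10, Npas4 by 1.38 ± 0.12 and Fos by 1.10 ± 0.13. NF-kB and inflammatory genes rose in 14 of 16 and fell in 0 (15 adjusted over the list alone, adjusted p = 5.51e-13, and adjusted p = 0.023 with an estimated correlation). At 1 µM against control peptide with DEX, Icam1 was at -0.72 ± 0.21, Birc3 at -0.71 ± 0.30 and Il1b at -1.03 ± 0.48. Vcam1 was at 0.14 ± 0.06, and none of these members passed there (smallest adjusted p = 0.07). Immediate-early genes rose in 16 of 24 and fell in 0 (18 adjusted over the list alone, adjusted p = 1.38e-18, and adjusted p = 0.023 with an estimated correlation), and cholesterol synthesis genes in 15 of 20 with 0 falling (17 adjusted over the list alone, adjusted p = 2.98e-12, and adjusted p = 0.0452 with an estimated correlation). Hypoxia and glycolysis genes fell in 18 of 21 and rose in 0 (19 adjusted over the list alone, adjusted p = 1.38e-18, and adjusted p = 0.0234 with an estimated correlation), with Pdk1 at -0.49 ± 0.03 and P4ha1 at -0.51 ± 0.03. With 1 sum per dose 9 immediate-early, 11 inflammatory and 8 cholesterol synthesis genes rose and 15 hypoxia and glycolysis genes fell. These lists passed there at the preset correlation (adjusted p = 8.65e-13, 6.87e-13, 1.02e-08 and 2.63e-12) and not with an estimated correlation (adjusted p = 0.377, 0.377, 0.384 and 0.377), and their means moved one way at every step of dose. Fkbp5 changed by -0.13 ± 0.03 and Tsc22d3 by -0.24 ± 0.04 per 10-fold dose, and Per1 (0.06 ± 0.04, adjusted p = 0.305) did not pass. Glucocorticoid-induced genes rose in 3 of 27 and fell in 4 (10 adjusted over the list alone, adjusted p = 0.827).

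Shox2 (-2.62 ± 0.66 per 10-fold dose) and Tcf7l2 (-1.21 ± 0.33), transcription factors of the thalamus, passed in this fit as well, but not with the libraries summed in pairs (adjusted p = 0.153 and 0.19). High values lay in 1 pair of libraries in each of the groups at 1, 3 and 10 µM. Tcf7l2 averaged 102 CPM in libraries 1 and 3 and 14.7 in libraries 2 and 4 at 1 µM, 11.6 and 72.7 at 3 µM, 9.46 and 45.5 at 10 µM, and 13.9 and 17.4 at 30 µM. With 1 sum per dose, which hides the difference between pairs, Tcf7l2 headed the genes ordered by p, at -1.22 per 10-fold dose. The diencephalic score went from 0.73 at 1 µM to 0.36, -0.02, -0.50 and -0.70 at the higher doses. G2/M genes rose at 1 µM in 3 of 21 and fell in 0 (11 adjusted over the list alone, adjusted p = 9.32e-08, and adjusted p = 0.107 with an estimated correlation). In all, 1642 genes rose and 1719 fell with dose. With libraries summed in pairs 1515 genes passed, with 1 sum per dose 1013, and without the 1 and 3 µM groups 1436.

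**Figure D3:**
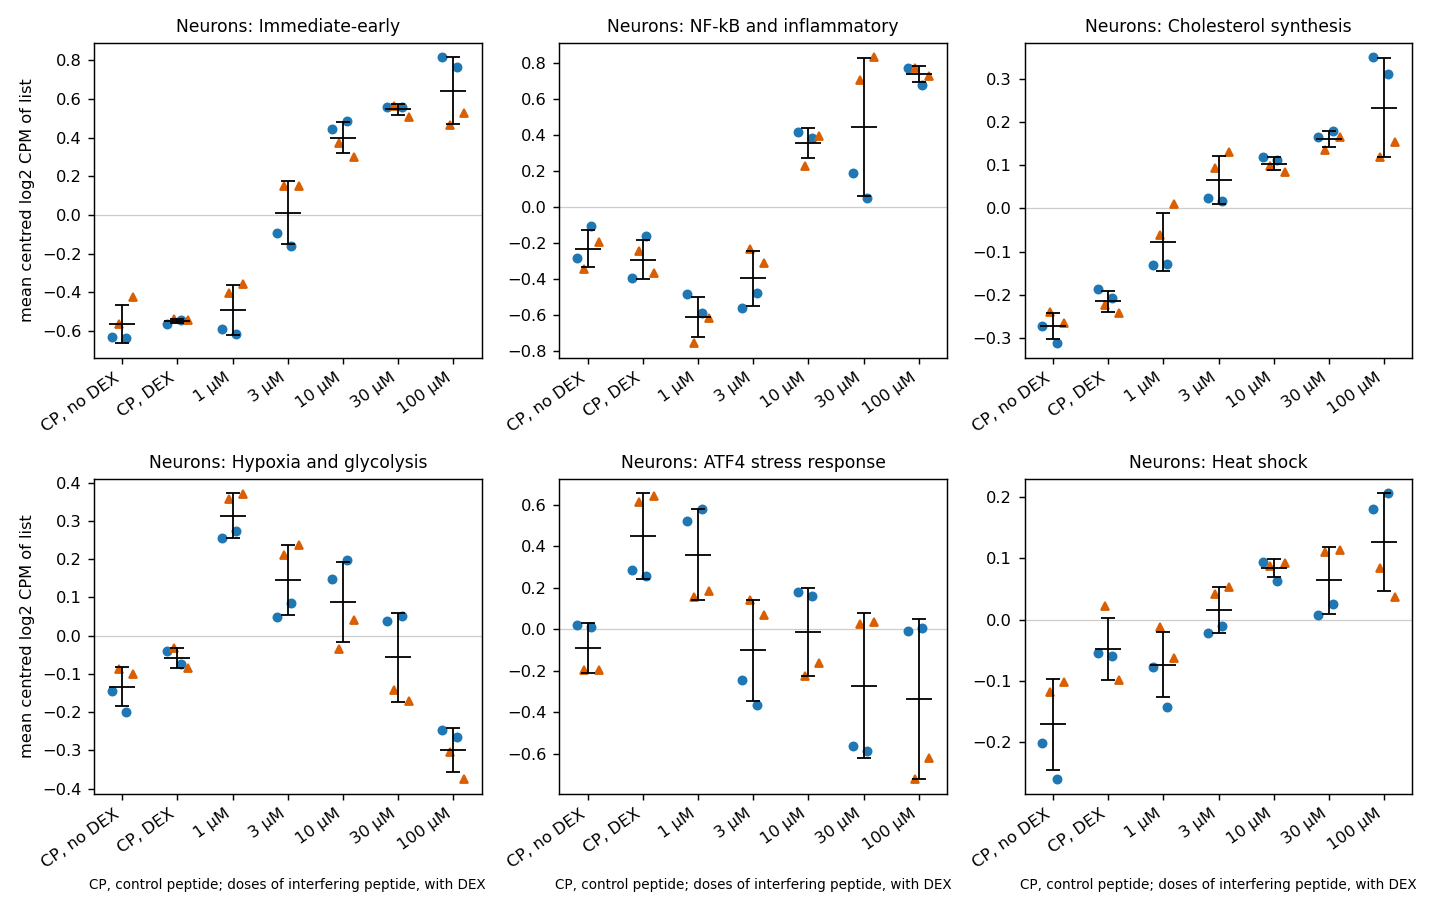
Mean centred log2 CPM of 6 gene lists in each neuron library, by group (CP, control peptide), with circles for replicates 1 and 3, triangles for replicates 2 and 4, and bars for mean ± SD. The immediate-early mean goes from -0.49 at 1 µM interfering peptide to 0.64 at 100 µM, and the hypoxia mean from 0.31 to -0.30.

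Genes called for DEX under control peptide, 200 in each direction, were followed over the interfering doses in libraries that took no part in choosing them. The set lowered by DEX scored from 0.06 ± 0.07 at 1 µM to -0.36 ± 0.03 at 100 µM interfering peptide. In the control peptide libraries, which chose the genes and so fix that difference, it scored 0.67 without DEX and -0.20 with it. Across the 20 libraries its score followed log10 dose with Pearson's r of -0.929 (permutation p = 1e-05, the smallest the resamples can give, adjusted 2e-05), Spearman's rho of -0.944 (permutation p = 1e-05) and r of -0.933 without the 2 libraries farthest from the median dose. These permutations moved single libraries, whereas dose was set for 5 groups, so their p-values are too small. The group means of the score fell at each step of dose. The diencephalic score, at 0.58 ± 0.88 without DEX and -0.45 ± 0.25 with it under control peptide, also went from 0.73 to -0.70 over these doses. The slope of the set's score per 10-fold dose was -0.20 ± 0.02, and -0.22 ± 0.02 with the diencephalic score as a covariate. The share of counts from the histone gene clusters was also lower with DEX than without, and lowest at 100 µM. It was not used as a covariate, so a shift in library make-up cannot be told apart from a dose response of the set. The set raised by DEX gave r of 0.272 (permutation p = 0.244) and rho of 0.227 (permutation p = 0.34), and 0.284 without those 2 libraries, and with 50 genes r was -0.17 (permutation p = 0.473). Its mean scores were 0.01, 0.01, 0.03, -0.02 and 0.06 at 1, 3, 10, 30 and 100 µM, and -0.21 without DEX and 0.12 with it in the libraries that chose its genes. Xist was at 2631 ± 85.2 CPM at 1 µM and 1.02 ± 0.32 at 3 µM, so the mix of animals differed between doses and the 20 libraries are not fully independent.

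Lists that did not pass in any neuron comparison had smallest adjusted p values by camera of 0.0783 for astrocyte markers, 0.0783 for neural progenitor markers, 0.0829 for glucocorticoid-induced genes, 0.116 for extracellular matrix genes, 0.163 for p53 targets, 0.17 for microglial markers and 0.258 for vascular and meningeal markers.

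**Figure D4:**
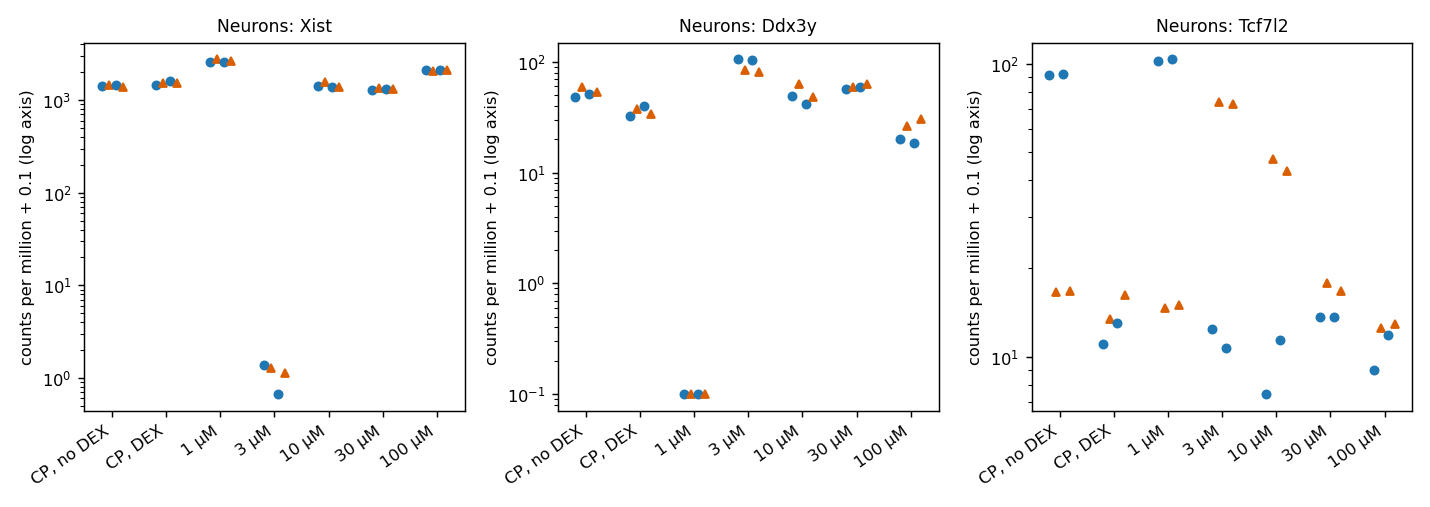
CPM plus 0.1, on a log axis, of Xist, the Y-chromosome gene Ddx3y and the thalamic gene Tcf7l2 in each neuron library, by group (CP, control peptide), with circles for replicates 1 and 3 and triangles for replicates 2 and 4. Ddx3y has 0 counts at 1 µM, Xist is near 1 at 3 µM, and Tcf7l2 differs between the pairs of libraries within several groups.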

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

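The tests of library scaling, of single libraries, of dexamethasone exposure, of cell mixture and of culture state described here, and the other splits of the samples, were chosen after the results were seen. The reassignment of doses to 5 summed dose groups was the one test whose prediction was written before its result.

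Single libraries stood apart from the other 3 of their group in 8 of 95 groups of values examined, where chance alone gives about 4.8. Fkbp5 was 1150 CPM in L929 full-length replicate 2 against 1090 to 1100 in the others, and 1350 CPM in delta-CC-LCD replicate 4 against 1300 to 1310. Sgk1 was 32.5 CPM in L929 control replicate 3 (others 28.3 to 29), 10.6 CPM in neuron control peptide without DEX replicate 2 (others 13.2 to 13.5) and 14.6 CPM at 3 µM interfering peptide replicate 4 (others 12.7 to 12.9). Nr3c1 was 21.6 CPM without DEX in replicate 3 (others 17.5 to 18), and Frmd5 was 83.5 CPM with control peptide and DEX in replicate 2 (others 89.6 to 90.4). The total was 17.1 M counts (M, 1e+06 counts) at 3 µM replicate 2, against 13.9 to 14.4 M. The deletion constructs, each against full-length, differed for interferon-response genes, with a median log2 difference of 2.30 between delta-IDR and delta-CC-LCD, and for glucocorticoid-induced genes, with a median of -0.25.

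Chance assignment of libraries to groups can be excluded for every comparison if the 4 libraries of a group are taken as independent, since in each only 1 of 35 splits of the 8 libraries, the real one, gave as many genes when the compared groups were fitted alone. If libraries 1 with 3 and 2 with 4, the most alike in most groups, count as 1 unit each, only 3 splits remain, too few for a share under 0.05. The splits do not bear on the animals, whose sex-linked genes differed between neuron groups. In L929 the real splits gave 8273, 9174 and 9184 genes for full-length, delta-IDR and delta-CC-LCD against control, where the highest other split gave 0, 1 and 1. They gave 3154 and 2173 genes for delta-IDR and delta-CC-LCD against full-length (highest other 0 in both) and 2922 between the deletions (highest other 1). For DEX the real split gave 1873 genes and the highest other 51. For interfering peptide against control peptide the real and highest other values were 341 and 132 at 1 µM, 370 and 99 at 3 µM, 709 and 17 at 10 µM, 2844 and 1 at 30 µM, and 3718 and 1 at 100 µM, and against no DEX 6290 and 1. For the trend, 1 of 100 assignments of doses to libraries gave as many as 3361 genes, and the highest other gave 2.

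Glucocorticoid-induced genes were far higher in all L929 construct groups than in control. Scaling between libraries is argued against, as a factor per library moves all genes alike, and the list's median log2 change from control to full-length lay 2.16 above that of all other tested genes (lower quartile of its members 1.64 above). A candidate explanation is that DEX was given to the construct groups and not to the control group, whose labels do not mention it. The smallest rise of the target score over control was 2.09, in delta-IDR, and control cells without the agonist would give such a rise as well. An effect of FRMD5 and a difference in DEX cannot be told apart, because no group separates them. The submitters' library names for the control and full-length groups share a stem and differ in a single letter, C against D. The meaning of the letters is not given, so it is also open whether the control cells lacked the construct.

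Interferon-response genes were higher in delta-IDR than in full-length. Scaling is argued against by a list median 3.07 above that of all other tested genes (lower quartile of its members 1.56 above), and a single library by the lowest delta-IDR library lying 1.60 above the highest library of the other groups. In the other deletion group the median change was 0.49, which leaves open a state of that one culture or line, such as a reaction to transfected nucleic acid, as a possible explanation. Such a state and an effect of the deletion cannot be told apart, because the labels name no more than 1 line per construct.

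Immediate-early genes rose with the dose of interfering peptide. For all genes as a set, differences between the groups' mixes of animals that do not follow dose are argued against. With 1 sum per dose only 1 of 60 dose orders, the real one, reached the real number of genes. That number takes in diencephalic genes such as Tcf7l2. The test was not run on immediate-early genes alone, so it cannot decide the question for them. A share of diencephalic cells that follows dose is argued against by the slope of the list score, 0.54 ± 0.07 with the diencephalic score as a covariate and 0.56 ± 0.06 without it. Within dose groups the list score changed by -0.01 ± 0.05 per unit of the diencephalic score. These errors take the 20 libraries as independent, whereas dose was set for 5 groups, so they are too small. The diencephalic list was also chosen after the values were seen. Handling or animals that follow the order of doses may remain. The score at 100 µM exceeded that of the same dose of control peptide by 1.19, a gap that handling or animals could leave as well. They cannot be told apart from the peptide because each dose is 1 group. The labels do not say how many cultures or animals a group came from. A response of the neurons to the peptide is thus one open hypothesis.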

How the results depend on the processing

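The sums of paired libraries, the sums per group, the trend without the 1 and 3 µM groups, the fits without X and Y genes, the diencephalic covariate and the additional splits were chosen after seeing the data, and the other alternatives beforehand. Libraries 1 and 3, and 2 and 4, were the most alike in 7 of 7 neuron groups and 3 of 4 L929 groups, although their counts differed by more than sampling noise (chi-square per gene from 2.28 upward). They were therefore not treated as 1 library deposited more than once, which does not show that they came from separate cultures. Summing these pairs gave 1501 genes for delta-CC-LCD against full-length and 2084 between the deletions. In neurons it gave 330 genes for DEX, 89, 101, 108, 700 and 1788 for interfering peptide at 1, 3, 10, 30 and 100 µM, and 1515 for the trend. These fits have fewer samples. With 1 sum per dose the trend held 1013 genes and without the 1 and 3 µM groups 1436, and with 1 sum per group DEX held 72. Fitting only the compared groups gave 370 genes at 3 µM, and the cause was not tested.

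Leaving out 1 library gave 7924 to 8116 genes for full-length, 8666 to 8897 for delta-IDR and 8763 to 9023 for delta-CC-LCD against control, 2893 to 3561 and 2091 to 2829 for the deletions against full-length, and 2509 to 3228 between them. In neurons it gave 1162 to 1796 for DEX, 228 to 428 at 1 µM, 436 to 1052 at 3 µM, 479 to 990 at 10 µM, 1892 to 2649 at 30 µM, 3325 to 4041 at 100 µM, 5350 to 5840 for 100 µM against no DEX and 2840 to 3441 for the trend. The libraries that moved a count by more than 1.5 times are named beside those counts in the report. DESeq2 and RLE size factors moved no count of genes by more than 1.5 times.

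The replicate numbers did not pair the samples. The mean correlation of same-numbered libraries across groups was -0.006 in L929 and -0.009 in neurons, and 3 of 16 and 3 of 28 libraries correlated best with their own number. With a replicate block the counts were 8301, 9058 and 9077 against L929 control, 3476, 2670 and 3059 among the constructs, 1836 for DEX, 375, 853, 834, 2691 and 4015 for the interfering doses, 6147 for 100 µM against no DEX and 3110 for the trend.

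Of 127 list results past the threshold, 26 passed with an estimated correlation, 117 with fry and 124 with the block. Of 759 values of named genes, 579 kept their side of the threshold with summed pairs, 757 with RLE, 735 with no filter and 750 with the block, and none reversed. DESeq2 kept 745 of 753. In the trend without the 1 and 3 µM groups, Rpl4 (-0.013), Rpl3 (-0.0001) and Rps4x (-0.0011) changed sign, and the cause was not tested. The median change of DEX genes at 100 µM was 0.11 (1652 genes) and 0.02 (859 genes) with libraries 1 and 3 or 2 and 4 used to call, and -0.012 without a split, where both changes share libraries. The simulations recovered 48% to 74% of the genes given the smallest change, at 1 depth and 1 number of libraries, so they do not show what depth adds. At this depth Frmd5 held 0 to 8 counts per L929 library and was not tested there.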

Other observations

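The tests described here were chosen after the values were seen, except those over the ER stress list, which was set before. In neurons the mean score of hypoxia and glycolysis genes was -0.06 ± 0.03 with control peptide and DEX, rose to 0.31 ± 0.06 at 1 µM interfering peptide, and went through 0.15, 0.09 and -0.06 to -0.30 ± 0.06 at 100 µM. Its slope per 10-fold dose was -0.29 ± 0.03, and -0.31 ± 0.04 with the diencephalic score as a covariate. ER stress genes rose in 6 of 18 and fell in 0 at 1 µM against control peptide with DEX (9 adjusted over the list alone, adjusted p = 7.35e-07, and adjusted p = 0.0577 with an estimated correlation), with Hspa5 at 0.30 ± 0.06. With dose 7 of them fell and 1 rose (8 adjusted over the list alone, adjusted p = 0.00107, and adjusted p = 0.14 with an estimated correlation), and their mean score went from 0.09 ± 0.04 at 1 µM to -0.08 ± 0.05 at 100 µM. Inflammatory genes had a slope of 0.71 ± 0.07, and 0.79 ± 0.09 with the covariate. For ATF4 targets the slope was -0.31 ± 0.09 and went to -0.19 ± 0.11 with the covariate. The errors of these slopes take the 20 libraries as independent, whereas dose was set for 5 groups, so they are too small.

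Counts from the histone gene clusters took 0.0804% ± 0.0075 of all counts without DEX and 0.0496% ± 0.0026 with DEX and control peptide. At 1, 3, 10, 30 and 100 µM interfering peptide they took 0.0501% ± 0.0025, 0.0617% ± 0.0013, 0.0511% ± 0.0027, 0.0429% ± 0.0036 and 0.0252% ± 0.0045. Group means rose at every step of dose in 554 of 17349 genes and fell at every step in 626, where a random order gives 145 on average. Genes that move together can depart far from that average without a peptide effect, and the diencephalic score also fell at every step. Of these genes 426 and 467 were among those called in the trend, which used the same libraries.

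Sex-linked genes differed between neuron groups, and some Y-chromosome genes also within them. Xist was at 2631 ± 85.2 CPM at 1 µM and 2149 ± 40.7 at 100 µM, and its means lay between 1352 and 1505 in both control peptide groups and at 10 and 30 µM, while at 3 µM it was 1.02 ± 0.32. Ddx3y was at 93.8 ± 13.7 CPM at 3 µM and 24.4 ± 5.77 at 100 µM. With control peptide it was at 51.3 ± 4.7 CPM without DEX and 35.3 ± 3.39 with DEX, and Eif2s3y at 68.9 ± 4.52 and 45.8 ± 4.26. The DEX comparison may thus also set different mixes of animals against each other. Kdm5d ran from 34 to 64.2 CPM among the libraries without DEX, and Uty from 6.45 to 12.7 at 100 µM.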
